A study of Mus musculus with 8 samples.

How the data were processed

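Gene expression was measured in single cells of dissociated kidney from C57BL/6 mice, a common inbred strain, by droplet capture with the 10x Genomics Chromium 3' chemistry, in which each captured transcript carries a unique molecular identifier (UMI) that is counted once. Per the labels, cisplatin, a platinum drug that crosslinks DNA and injures kidney tubules, was given intraperitoneally at 20 mg/kg and kidneys were taken 3 or 7 days later, and sham mice received saline by the same route. The labels put 8 libraries into 3 groups: 3 sham, 2 at day 3 and 3 at day 7. The series' design text speaks of 3 biological repeats, and 2 day 3 libraries were analysed here. Neither the labels nor the design text says whether the libraries of a group came from separate mice, so the p-values measure the spread between these libraries, part of which may be technical.

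The deposited matrices hold whole-number UMI counts per gene and cell barcode, with no normalization, as their values show. The submitters' processing notes name bcl2fastq, Cell Ranger 3.1.0, Seurat 3.1.1 and the genome build GRCm38. The annotation release and the rule by which barcodes were selected are not given in the sources used here. All 55450 gene IDs were found among the 55536 genes of a GENCODE annotation of GRCm38, from which coordinates were taken. The 3' tag counts the end of a transcript, so isoforms are not told apart. Members of gene families with near-identical copies can share reads, which makes the levels of Gsta1, Hspa1a, Hspa1b, Mt1, Mt2, Slc22a28, Acsm2, Ces2e, the H2 genes and Hist1h2ae uncertain, and the same holds for genes that overlap another gene.

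Barcodes were kept with at least 200 genes, at least 500 UMIs and under 50% of UMIs from mitochondrially encoded genes, a wide limit because tubule cells hold many mitochondria. Doublets were scored per library with Scrublet in scanpy 1.11.5, and the cells of highest score were removed at the rate of 0.8% per 1000 cells. The automatic Scrublet threshold marked between 0.073% and 1.55% of a library's cells and served as an alternative. Kept cells of all libraries were scaled to 10000 UMIs and log-transformed, and 2000 variable genes, 30 principal components and 15 nearest neighbours gave Leiden clusters at resolution 1 (igraph 0.11.9), with no batch integration.

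Each of the 33 clusters was named from marker genes fixed in advance. A cluster took the class with the highest mean marker level among classes with at least 3 markers detected in at least 25% of its cells, and a joint name where a second class reached a ratio of 0.8 to the first. It stayed unnamed where its 10 leading genes held more markers of another class, or where it had few UMIs and no own marker among them. This scoring rule was set after the files had been looked at, and it left 4 clusters unnamed. Classes are called proximal-tubule-like and so on because they rest on markers alone. Libraries were compared within their groups by a chi-square test over genes, whose statistic per degree of freedom lay between 32.0 and 476.6, so no library was a copy of another.

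Samples were the replicates. UMI counts were summed per class and library (class sums), and libraries with at least 20 cells of a class entered the fit of that class, a group needing at least 2 of them. One edgeR 4.0.16 quasi-likelihood fit over the 3 groups (R 4.3.3, TMM factors, filterByExpr) gave log2 fold changes, standard errors and Benjamini-Hochberg adjusted p-values over all genes tested, with calls at an adjusted p under 0.05. The 3 groups shared one estimate of the spread because day 3 has 2 libraries. Levels shown as CPM are counts scaled to a common total of each class sum, without TMM factors, which entered only the edgeR fit. Cell numbers per class were tested with the same edgeR test without TMM, the kept cells of a library being its library size. Exact two-sided permutation tests of class shares and of shares of cells with a UMI cannot go below p = 0.1 in either 3 against 3 or 3 against 2 libraries. For the latter shares each cell was thinned to 1000 UMIs and shallower cells were left out. Intervals are exact binomial at 95% and, like the floor of 3 counts used for a total of 0, cover counting error only. A fold against 1 to 3 UMIs is given as the ratio of summed UMIs with its counting interval.

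Gene lists were tested with camera (limma 3.58.1), which compares a list with the other genes tested, at its preset correlation of 0.01 and again with a correlation estimated from the data, adjusted over the lists of a class. The 26 lists cover injured tubule, p53 targets, proximal tubule transporters, fatty acid oxidation, nuclear-encoded respiratory chain, mitochondrially encoded genes, glycolysis, gluconeogenesis, cell cycle, NRF2 and glutathione, chemokines and NF-kB response, interferon response, antigen presentation, regulated cell death, endoplasmic reticulum stress, immediate early and dissociation genes, extracellular matrix and TGF-beta, developmental tubule regulators, androgen-regulated and sex-biased proximal tubule genes, resident, monocyte-derived and repair-phase macrophages, cytotoxic lymphocytes, T cell activation and exhaustion, endothelial activation, and thick ascending limb transport. Proximal tubule transporters were tested in the other classes as a measure of free RNA.

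Genes to be named were set by rule. In each comparison within a class these were called genes with a mean of at least 50 CPM and no overlap between the CPM values of the groups, ranked by the size of the log2 fold change, the first 6 higher and 6 lower in proximal-tubule-like cells against sham and 4 and 4 elsewhere. Left out of the ranking were predicted gene models, mitochondrially encoded, ribosomal protein, haemoglobin, immunoglobulin and T cell receptor genes and sex-linked genes used to tell males from females, and outside the proximal tubule also genes under 20% of their mean CPM in any other class. The 2 to 4 members of each described list with the smallest p were added, and Havcr1, Lcn2, Cdkn1a, Mt1 and Mt2 were named in both proximal tubule comparisons against sham. A few genes that this rule names are not reported here. Genes of any other kind that are named are said to be chosen after their values were seen. Groups, tests, lists, markers, the rule for named genes and the alternatives were chosen before the data were examined, except where an alternative is said to be added.

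The procedure was tested on simulated data with 200 changed genes per run drawn from the real means and library sizes. For proximal-tubule-like sums it recovered 40.7%, 72.7% and 84% of 4-, 8- and 16-fold changes at day 3 (14056 genes run) and 56.7%, 80.7% and 92% at day 7 (14040 genes run), but 0.7% and 3.3% of 2-fold changes. False calls made up 16.5% of the calls in endothelial-like sums at day 3 (7808 genes run) and 14.8% in mononuclear-phagocyte-like sums at day 3 (11286 genes run), and between 5.9% and 8.9% in the other comparisons, so the nominal 5% was exceeded. With nothing changed, 16 and 5 genes were called in those first 2 comparisons. The test of class shares was run on 50 simulated data sets per comparison, in each of which a class was lowered 8-fold. These were drawn with a fixed spread between libraries. The test recovered 48, 50 and 50 of the changes at day 3, at day 7 and between the days. It also made 21, 29 and 36 calls of unchanged classes, so the nominal 5% was exceeded there too.

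Alternatives were DESeq2 1.42.0, RLE size factors in edgeR, no filterByExpr, a fit on only the 2 groups compared, the replicate number as a block, under 25% mitochondrial UMIs, no doublet removal, the automatic Scrublet threshold, Leiden resolution 2, class sums thinned to the smallest library, other thinning of cells (500 UMIs or none), TMM over the classes, the exact test for shares, and each library left out in turn. A minimum of 200 UMIs per cell, and proximal-tubule-like cells without the cluster led by Krt20, were added after seeing the data. Single-cell steps used Python 3.11.15 with anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9, and tables were handled in R with data.table, version 1.17.8.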

Results

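Single-cell transcriptomes of kidney were compared between saline-injected sham mice and mice taken 3 or 7 days after 1 injection of cisplatin. Sham replicates 1 to 3 held 6772, 5824 and 4810 barcodes with 33631982, 31704787 and 33740650 UMIs in all. Day 3 replicates 1 and 2 held 5778 and 4472 barcodes with 45710768 and 40986583 UMIs, and day 7 replicates 1 to 3 held 9179, 6199 and 4976 barcodes with 75099597, 4555638 and 28651500 UMIs. Day 7 replicate 2 was the shallowest, with a median of 627 UMIs per barcode and 2391 barcodes under 500 UMIs. Barcodes with at least 50% mitochondrial UMIs made up 45.2%, 47.6% and 39.8% in sham, 5.83% and 19.9% at day 3, and 20.4%, 2.37% and 17.7% at day 7, and they were left out. After filtering, 3587, 2957 and 2819 sham cells, 5201 and 3472 day 3 cells, and 6881, 3691 and 3959 day 7 cells were kept. Their median depths were 4513, 4931 and 6739 UMIs in sham, 4792 and 6252 at day 3, and 7131, 889 and 4949 at day 7. Beside a level or a share, ± is the SD over libraries, and beside a log2 fold change it is the standard error, with n = 3 sham, n = 2 day 3 and n = 3 day 7 libraries unless said otherwise.

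Of 11 cell classes, 4 had a changed share of the kept cells at day 7 and 1 at day 3, which has fewer libraries. In simulated data this test made 29 false calls beside 50 recovered changes at day 7, and 21 beside 48 at day 3. Mononuclear-phagocyte-like cells made up 24.9 ± 1.37% of kept cells in sham and 1.96 ± 1.16% at day 7, a log2 change of -3.67 ± 0.78. Endothelial-like cells fell from 7.50 ± 3.28% to 0.745 ± 0.170%, dendritic-like cells from 5.79 ± 0.763% to 0.803 ± 0.645% and stromal-like cells (fibroblasts and mural cells) from 2.54 ± 1.07% to 0.259 ± 0.0509%. At day 3 the share of cells resembling distal convoluted or connecting tubule fell from 2.32 ± 0.476% to 0.0624 ± 0.0339%, a log2 change of -5.20 ± 0.87. The day 3 libraries held 2 and 3 such cells (counting intervals 0.005% to 0.139% and 0.018% to 0.252%). Cells were named by markers, and whether cells of this segment were named otherwise at day 3 was not tested. This share was higher again at day 7, by 6.34 ± 0.91 on the log2 scale against those few day 3 cells. Neutrophil-like cells made up 19.4% and 3.44% of the day 3 libraries against 2.15 ± 1.99% in sham, which did not pass the test. They fell from day 3 to day 7 by 5.12 on the log2 scale. Proximal-tubule-like cells made up 44.8 ± 2.77% in sham, 70.6% and 21.6% in the day 3 libraries and 74.0 ± 9.55% at day 7, where the edgeR adjusted p was 0.261. Shares of thick-ascending-limb-like cells (0.915 ± 0.284% in sham, 1.27 ± 0.440% at day 3 and 2.08 ± 0.518% at day 7), T/NK-like cells (6.38 ± 3.66%, 5.36 ± 6.36% and 5.66 ± 3.50%), B-like or plasma-like cells, and cells resembling intercalated or collecting duct principal cells did not pass the test in either comparison with sham.

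**Figure D1:**
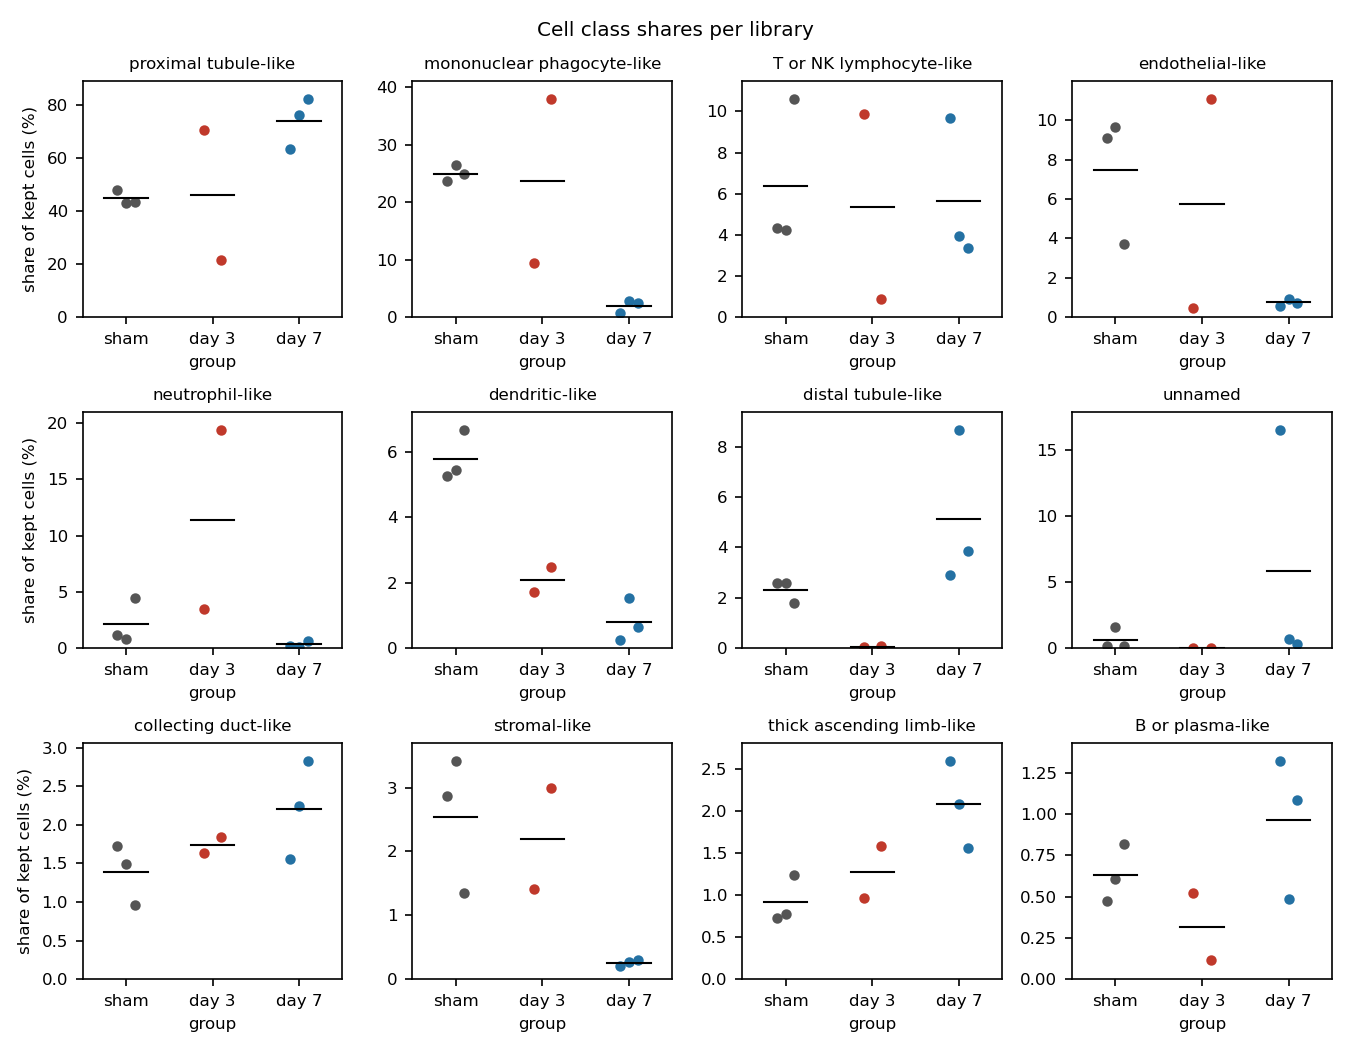
Share of kept cells in % (vertical axes, linear) of each cell class, 1 dot per library in the sham, day 3 and day 7 groups (horizontal axes), with bars at group means. The mononuclear-phagocyte-like dots of day 7 all lie below those of sham, while the 2 day 3 libraries hold 70.6% and 21.6% proximal-tubule-like cells.

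In the edgeR test of cell numbers, the day 7 falls against sham had adjusted p-values of 0.00687 for mononuclear-phagocyte-like, 0.00566 for stromal-like, 0.0105 for dendritic-like and 0.0298 for endothelial-like cells, and the day 3 fall of distal convoluted or connecting tubule had 0.00262. Of 11 classes, 1 changed at day 3, 4 at day 7, and 4 between the days, the last being distal convoluted or connecting tubule, mononuclear-phagocyte-like (-3.59 ± 0.81), neutrophil-like and stromal-like cells (-3.08 ± 0.64). Each of these comparisons reached the smallest p that an exact permutation test of the shares allows, 0.1, except that of distal convoluted or connecting tubule between the days (exact p = 0.2), and none passed after adjustment. The endothelial-like fall lost its call without sham replicate 1 (edgeR adjusted p = 0.0633) and without day 7 replicate 1, 2 or 3 (0.0832, 0.0799 and 0.0687). With day 3 replicate 2 left out the count was 2 classes at day 3, endothelial-like cells being added (-4.07, edgeR adjusted p = 0.0141). It was 2 between the days, since mononuclear-phagocyte-like and neutrophil-like cells then missed the threshold (both 0.0545). Without day 3 replicate 1, 8 classes differed between the days. A share can rise only where another falls, and tissue dissociation sets which cells are captured. The minimum of 500 UMIs removed barcodes from day 7 replicate 2 only. The limit of 50% mitochondrial UMIs removed more of the sham than of the day 3 and day 7 barcodes, and shares with a wider limit were not tested. All unnamed clusters were nearest to proximal tubule but had more markers of another class among their leading genes. They held 16.5% of day 7 replicate 1 and 0.677% and 0.303% of the other day 7 libraries. In the sham libraries they held 0.139%, 1.62% and 0.142%, and they held no day 3 cell.

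Cisplatin is taken up by the proximal tubule, the segment that reabsorbs most of the filtered solutes, and its cells at day 3 were compared with sham to show what injury changed there. Called rises were found for 21 of 28 p53 targets, 8 of 22 injured tubule genes, 7 of 25 chemokine and NF-kB genes and 6 of 23 NRF2 and glutathione genes. These 4 lists passed the camera test at its preset correlation and not with an estimated one (adjusted p = 0.101, 0.144, 0.144 and 0.148 with an estimated correlation). Among the largest rises were those of Sprr1a, a cornified envelope protein, Krt20, an intermediate filament keratin, and Lcn2, a lipocalin used as a marker of tubular injury. Sprr1a went from 0.311 ± 0.315 CPM in sham to 414 ± 291 CPM, a log2 fold change of 10.19 ± 0.95. Krt20 went from 0.420 ± 0.182 to 326 ± 336 CPM (9.33 ± 0.90) and Lcn2 from 0.123 ± 0.0341 to 94.4 ± 93.6 CPM (9.22 ± 1.12). Cdkn1a, the cyclin-dependent kinase inhibitor that p53 induces, rose from 13.9 ± 6.70 to 947 ± 613 CPM (5.81 ± 0.67). Gatm, which starts creatine synthesis, fell from 1574 ± 949 to 44.3 ± 12.6 CPM (-5.34 ± 1.17) and the methyltransferase gene Inmt from 388 ± 193 to 13.8 ± 0.807 CPM (-5.05 ± 0.77).

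Of 14470 genes tested, 620 changed at an edgeR adjusted p under 0.05, 473 higher and 147 lower, and 3501 had an unadjusted p under 0.05. The CPM values of the groups did not overlap for any of the 620, and for 44.4% of all genes tested, where chance gives 20%. Further ranked rises were those of the carboxylesterase gene Ces2e (5.63), the glutathione transferase gene Gsta1 (4.99) and the antiproliferative gene Btg2 (4.68, from 23.4 ± 3.90 to 722 ± 41.5 CPM). Further ranked falls were those of Clec2h (-5.93), the organic anion transporter gene Slc22a28 (-4.84) and the brush border dipeptidase gene Dpep1 (-4.33). The edgeR adjusted p-values were 0.00689 for Sprr1a and Krt20, 0.00689 for Lcn2, 0.00689 for Cdkn1a, 0.0395 for Gatm and 0.0141 for Inmt. Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976–29100727 on GRCm38), Krt20 (ENSMUSG00000035775, chromosome 11, 99428403–99438150), Sprr1a (ENSMUSG00000050359, chromosome 3, 92483952–92485895), Lcn2 (ENSMUSG00000026822, chromosome 2, 32384633–32388252), Gatm (ENSMUSG00000027199, chromosome 2, 122594467–122611303) and Inmt (ENSMUSG00000003477, chromosome 6, 55170626–55175043) are protein-coding genes.

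The count of called genes moved with single libraries: it was 244, 7 and 0 without sham replicates 1 to 3 and 2157 and 25 without day 3 replicates 1 and 2. Without day 7 replicates 1 to 3, which share the estimate of the spread, it was 254, 968 and 1037. Different clusters held the class in the 2 groups. Clusters 2, 18, 25 and 8 held 35.4%, 23.7%, 10.7% and 18.9% of day 3 replicate 1. They held 17.8%, 2.9%, 66.0% and 11.2% of replicate 2. Clusters 7 and 0 each held between 14.8% and 27.5% of the sham libraries. Cluster 4 held 32.0%, 0.2% and 0.2% and cluster 16 held 0.8%, 5.8% and 35.7% of sham replicates 1 to 3. DESeq2 called 1773 genes, and edgeR called 2625 without filterByExpr and 367 with thinned sums. Gatm, Inmt, Clec2h and Slc22a28 led clusters 13, 0, 16 and 17. Cluster 25 was led by Krt20, Sprr1a, Cdkn1a, Tnfrsf12a and Trp53inp1 and had low levels of proximal tubule markers, of which 18 of 30 were detected. Without it, an alternative added after seeing the data, 127 genes were called. Cdkn1a (4.71), Krt20 (7.31), Lcn2 (10.47), Btg2 (5.02) and Inmt (-6.01) were still called. Sprr1a (4.73), Gatm (-4.90), Clec2h (-5.37), Slc22a28 (-4.61), Dpep1 (-3.86) and Gsta1 (4.70) were not. Other genes named below that lost their call there were Krt18 (2.10), Timp1 (5.25), Slc26a1 (-2.17), Acsm1 (-1.20), Isg15 (1.53), Rsad2 (0.42), Bak1 (1.49), Ppp1r15a (1.02) and Cd24a (1.07).

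**Figure D2:**
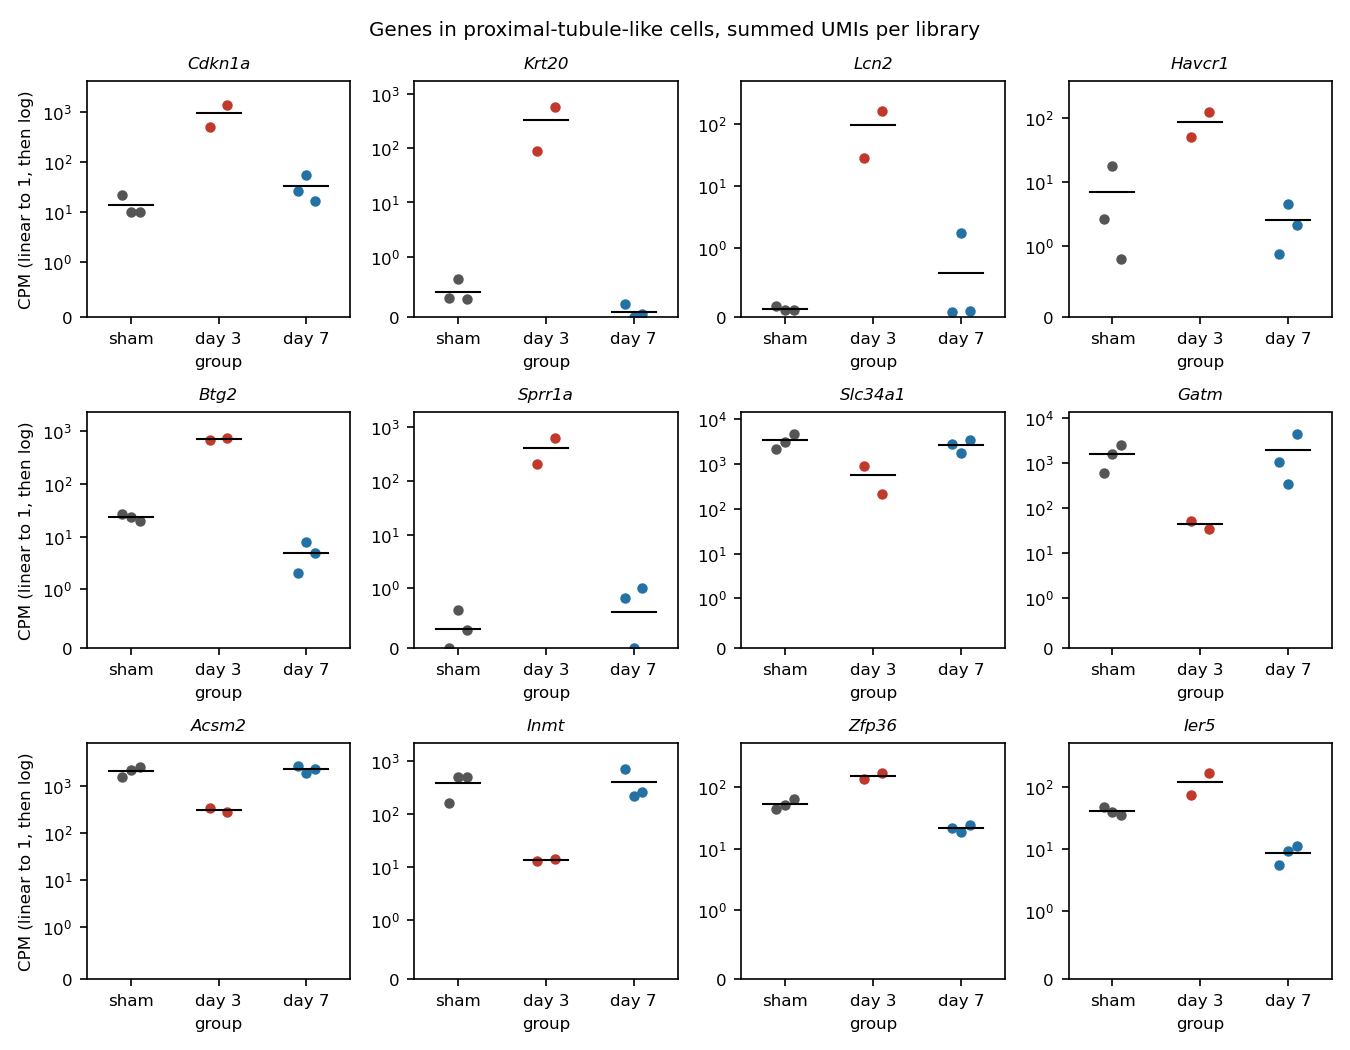
Level of 12 genes in proximal-tubule-like cells in CPM (vertical axes, linear up to 1 and logarithmic above), 1 dot per library by group (horizontal axes), with bars at group means. Cdkn1a, Krt20, Sprr1a and Lcn2 lie higher and Gatm, Inmt and Acsm2 lower in both day 3 libraries than in all 3 sham libraries.

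Of 28 p53 targets tested 21 rose (26 adjusted over the list alone), none fell and the median log2 fold change was 2.60. Beside Cdkn1a and Btg2, Trp53inp1 (3.29) and the mitotic spindle gene Psrc1 (6.19) rose. The list had a camera adjusted p of 2.66e-37 (adjusted p = 0.101 with an estimated correlation). All 22 injured tubule genes were higher and 8 of them rose (18 adjusted over the list alone; median 3.29), including Krt18 (5.12, and 2.10, not called, without the cluster led by Krt20) and Clu (3.69), which encodes clusterin. The list had a camera adjusted p of 2.45e-15 (adjusted p = 0.144 with an estimated correlation). Krt20, Krt18, Clu and Lcn2 belong to that list, and Cdkn1a and Btg2 to the p53 list. Havcr1, which encodes the injury marker KIM-1, stood at 86.7 ± 51.4 CPM against 7.05 ± 9.30 in sham (3.29 ± 1.02, edgeR adjusted p = 0.0942) and was not called. The metallothionein genes Mt2 (4.68, edgeR adjusted p = 0.0583) and Mt1 (3.32, 0.0905) were not called either.

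Of 25 chemokine and NF-kB genes 7 rose (14 adjusted over the list alone; median 1.47), with Cxcl1, a neutrophil attractant, at 4.29 and the cytokine receptor gene Tnfrsf12a at 3.95. This list had a camera adjusted p of 5.26e-11 (adjusted p = 0.144 with an estimated correlation). NRF2 and glutathione genes, which detoxify electrophiles, rose in 6 of 23 cases (13 rose and 1 fell adjusted over the list alone; median 1.35), with the epoxide hydrolase gene Ephx1 at 6.46 and sulfiredoxin, Srxn1, at 2.96. Their camera adjusted p was 1.33e-05 (adjusted p = 0.148 with an estimated correlation). Extracellular matrix genes rose in 6 of 18 cases (8 rose and 1 fell adjusted over the list alone; median 1.33; camera adjusted p = 0.00276, adjusted p = 0.411 with an estimated correlation). Among them the protease inhibitor gene Timp1 was at 5.52 (5.25, not called, without the cluster led by Krt20). RNA of 5 other classes, scaled by their markers, made up between 0 and 0.590% each of the proximal-tubule-like UMIs of the day 3 libraries, neutrophils 0.0103% and 0.119%.

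Of 43 transporters 1 fell over all genes, the sulfate transporter Slc26a1 (-2.50, and -2.17, not called, without the cluster led by Krt20), and 6 fell and 1 rose adjusted over the list alone. The median was -0.81 and the camera adjusted p 4.33e-06 (adjusted p = 0.418 with an estimated correlation). Slc34a1, the sodium-phosphate cotransporter (ENSMUSG00000021490, chromosome 13, 55398187–55415592), stood at 572 ± 499 CPM against 3382 ± 1278 in sham (-2.76 ± 0.68) with an edgeR adjusted p of 0.0527. All 52 nuclear-encoded respiratory chain genes were lower with a median of -0.44, and none of them was called. Sdha and Atp5c1, at -1.16 and -1.04, had the smallest p, and the list had a camera adjusted p of 1.42e-05 (adjusted p = 0.656 with an estimated correlation). None of the 13 mitochondrially encoded genes was called, and their list was lower (median -1.09; mt-Nd4 -1.75 and mt-Nd3 -1.79; camera adjusted p = 2.27e-04, adjusted p = 0.358 with an estimated correlation). The median mitochondrial shares of all kept cells were 16.9%, 16.1% and 8.29% in sham and 8.28% and 7.50% at day 3. Gluconeogenesis was lower as a list of 10 genes, none called and 2 that fell adjusted over the list alone (median -0.70, Pcx -1.56, Fbp1 -1.69). So were 9 androgen-regulated and sex-biased genes, none called and 1 that fell adjusted over the list alone (median -0.83). Their camera adjusted p-values were 0.00420 and 0.0262 (adjusted p = 0.418 and 0.563 with an estimated correlation). Without day 3 replicate 2 the calls of transporters, gluconeogenesis (camera adjusted p = 0.153 for both) and androgen-regulated genes (0.412) were lost. The last was also lost without sham replicate 2 (camera adjusted p = 0.0857), and gluconeogenesis without the cluster led by Krt20 (0.361).

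In 9 further lists the camera test found no shift, though single members moved. Acsm2 (-3.00) and Acsm1 (-1.48), 2 medium-chain acyl-CoA synthetase genes, fell among 37 fatty acid oxidation genes (camera adjusted p = 0.165). Interferon-induced Isg15 (4.46) and Rsad2 (5.84) rose among 24 interferon response genes (0.0533), and 3 rose adjusted over the list alone. Both calls were lost without the cluster led by Krt20, where Isg15 was at 1.53 and Rsad2 at 0.42, as were those of Ppp1r15a (1.02), Cd24a (1.07), Bak1 (1.49) and Acsm1 (-1.20). Among 20 genes of regulated cell death (0.0685) Bak1 rose (1.62), and so did Mlkl, the effector of necroptosis, with 100 UMIs against 1, a ratio of 82.7 (counting interval 14.5 to 3300). Mlkl did not pass filterByExpr without the cluster led by Krt20 and was not tested there. Ppp1r15a (3.45) rose among 21 endoplasmic reticulum stress genes, whose median was -0.14 and mean 0.57 (camera adjusted p = 0.673). Zfp36 (1.29) and 2 more rose among 26 immediate early genes (0.0685), and Cd24a (4.51) among 15 developmental regulators, whose median was -0.42 and mean 0.11 (0.531). No gene was called among 15 glycolysis genes (median -0.10, mean 0.58, camera adjusted p = 0.804), 27 cell cycle genes (0.649) or 19 antigen presentation genes (0.540). Adjusted over the list alone, 4, 3 and 7 genes rose in the death, stress and immediate early lists, and 2 fell in the last. Of 19 lists, 10 passed at the preset correlation and 0 with an estimated one, where 14470 genes were tested.

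**Figure D3:**
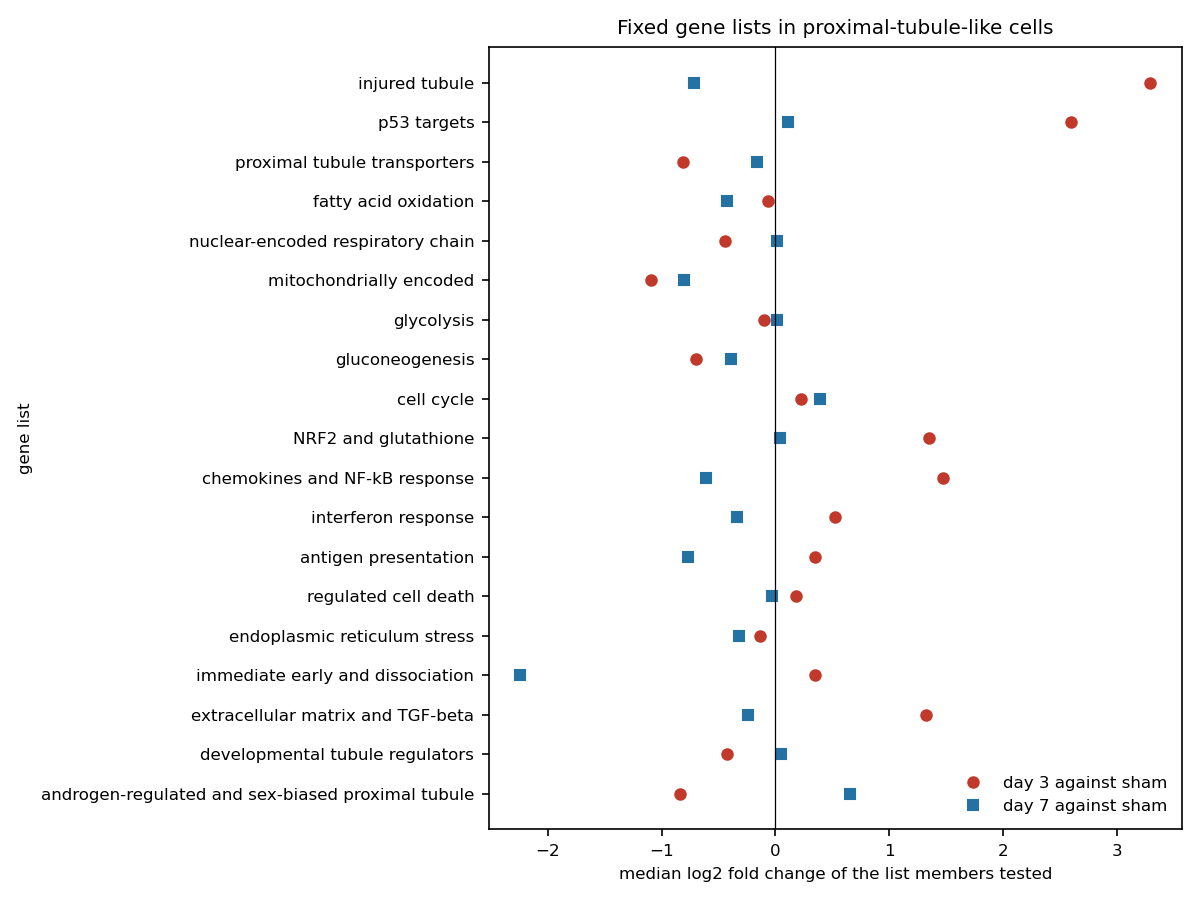
Median log2 fold change against sham (horizontal axis) of the members of 19 gene lists (vertical axis) in proximal-tubule-like cells, circles for day 3 and squares for day 7. The p53 list has its median at 2.60 at day 3 and 0.11 at day 7, and the immediate early list at 0.35 and -2.24.

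At day 7 none of the genes called in proximal-tubule-like cells at day 3 was called against sham. Cdkn1a was at 32.4 ± 20.1 CPM (0.85 ± 0.54 against sham), Lcn2 at 0.35 ± 1.67, Havcr1 at 2.51 ± 1.87 CPM (-2.17 ± 1.05), Mt2 at -2.40 ± 1.09 and Mt1 at -1.58 ± 0.91. None of them was called. Immediate early and dissociation genes, transcription factor and heat shock genes that cells induce within minutes of handling or stress, were lower as a list (camera adjusted p = 4.18e-37, adjusted p = 0.0837 with an estimated correlation). The median was -2.24 over 26 genes, with 0 called over all genes and 18 that fell adjusted over the list alone. Zfp36, an mRNA-destabilising protein gene, was at -1.56 ± 0.24 and Ier5 at -2.57 ± 0.40. No gene passed the edgeR threshold among 14470, while 1173 had an unadjusted p under 0.05. DESeq2 called 156, and edgeR called 619 without filterByExpr and 7 without day 7 replicate 3. The groups did not overlap for 21.7% of genes, where chance gives 10%.

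The summed level of the immediate early list overlapped between the groups, with 3375 CPM in day 7 replicate 3 and 3290.0 CPM in sham replicate 1. Of 19 lists 7 passed at the preset correlation, 12 without day 7 replicate 2, and 0 with an estimated correlation. Mitochondrially encoded genes were lower too (median -0.80, mt-Nd4 -2.54), 5 falling and 1 rising adjusted over the list alone. Their camera adjusted p was 1.27e-10 (adjusted p = 0.203 with an estimated correlation), and the median mitochondrial shares at day 7 were 12.2%, 7.17% and 6.39%. Antigen presentation genes were lower with a median of -0.77 (B2m -1.78, Cd74 -2.71) and 6 that fell adjusted over the list alone, and chemokine genes with a median of -0.61 and 3 such genes. Endoplasmic reticulum stress (-0.32, Atf3 -4.10), interferon response (-0.34) and fatty acid oxidation genes (-0.42, Acsl1 -2.02) were also lower, with 1, 1 and 0 such genes. In this order the camera adjusted p-values were 3.63e-08, 1.59e-05, 1.28e-04, 0.0201 and 1.42e-04 (adjusted p = 0.488, 0.463, 0.463, 0.875 and 0.875 with an estimated correlation). Cxcl2, a chemokine gene, had 3 UMIs against 48, a ratio of 32.5 (counting interval 10.5 to 163), and was not called. The fatty acid oxidation call was lost without sham replicate 1 (camera adjusted p = 0.191) or day 7 replicate 3 (0.0888). That of interferon response was lost without sham replicate 3 (0.796), day 3 replicate 1 (0.0793), day 3 replicate 2 (0.0704) or day 7 replicate 1 (0.636), and also under 25% mitochondrial UMIs (0.207) and at Leiden resolution 2 (0.0753).

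The 12 remaining lists did not pass at day 7, with camera adjusted p-values of 0.102 for transporters (median -0.16, mean 0.03, lower by the test), 0.102 for extracellular matrix, and 0.126 for gluconeogenesis. They were 0.136 for injured tubule (-0.72; Clu 2.09, S100a11 1.97, Spp1 -2.70), 0.190 for cell cycle (Mki67 1.78), 0.497 for androgen-regulated genes (Cyp7b1 4.12) and 0.506 for regulated cell death. For p53 targets it was 0.740 (median 0.11, mean 0.01, lower by the test), with 2 that fell adjusted over the list alone, Btg2 (-2.67) and Plk3 (-1.71). It was 0.740 for the respiratory chain (median 0.02, lower by the test), 0.740 for developmental regulators (median 0.05, mean -0.15), 0.755 for NRF2 and glutathione (median 0.04, mean -0.01) and 0.941 for glycolysis. Clusters 26, 20 and 16 held the most cells of day 7 replicates 1, 2 and 3 (34.2%, 69.8% and 36.1%). Of the 1991 cells of cluster 20, 1966 came from day 7 replicate 2.

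The contrast of day 7 with day 3 tested the difference between the stages itself. Here 1095 genes were called, 295 higher and 800 lower at day 7. Krt20 was at -11.07 ± 0.98 on the log2 scale, Cdkn1a at -4.95 and Btg2 at -7.35 ± 0.55, while Gatm (5.46 ± 1.18) and Inmt (4.82 ± 0.76) were higher. p53 targets fell in 23 of 28 cases (25 adjusted over the list alone; median -2.70), chemokines in 15 of 25, immediate early genes in 13 of 26 and injured tubule genes in 11 of 22. In this order camera adjusted p-values were 7.70e-34, 1.22e-16, 6.66e-17 and 3.37e-16 (adjusted p = 0.1 for p53 targets and 0.128 for the others with an estimated correlation). The count was 72 without day 3 replicate 2, 91 without day 7 replicate 1, 623 and 647 without sham replicates 2 and 3, 2939 without day 3 replicate 1, and 504 without the cluster led by Krt20.

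No gene was called in the same direction in both comparisons with sham, and 0 would be by independent lists, since no gene was called at day 7. DESeq2 found 29 and edgeR 201 without filterByExpr and 3 without day 7 replicate 3. Log2 fold changes of day 3 and day 7 had the same sign for 55.9% of 14470 genes and a correlation of 0.211 across genes, which are not independent replicates. Both share the sham libraries. In 20 simulations every library, sham included, was drawn anew with no group changed, and this gave 64.9% and 0.443 on average. The covariance was 0.244 against 0.142 simulated, a difference of 0.102. The 3 sham libraries cannot be split into groups of 2, so the part owed to shared controls was not separated.

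Cells with a Havcr1 UMI were counted because its level in sums can hide how many cells carry it. Havcr1 (ENSMUSG00000040405, chromosome 11, 46735080–46779578) was seen in 3.78% and 7.83% of proximal-tubule-like cells thinned to 1000 UMIs in the day 3 libraries, a mean of 5.81% ± 2.87, against 0.445% ± 0.697 in sham and 0.145% ± 0.0814 at day 7. The exact p was 0.1 for day 3 against sham, the smallest possible, and 0.9 for day 7 against sham. Over the family of 6 genes the exact permutation test gave an adjusted p of 0.225 at day 3. Without thinning the means were 18.0%, 1.21% and 0.495%. As background, Havcr1 was seen in 0.294% of 340 endothelial-like cells of day 3 replicate 2 (counting interval 0.0074% to 1.63%) and 0.452% of 443 T/NK-like cells of day 3 replicate 1 (0.0547% to 1.62%). The 16 endothelial-like cells of day 3 replicate 1 and 27 T/NK-like cells of day 3 replicate 2 held none, with upper limits of 20.6% and 12.8%, too few to bound it. Median depths were 9499.5 UMIs in the proximal-tubule-like and 3884.5 UMIs in the endothelial-like cells of day 3 replicate 2. Thinning left out 214, 147 and 87 sham, 338 and 87 day 3, and 226, 1527 and 159 day 7 cells. Cdkn1a was seen in 25.3% and 53.2% of cells in the day 3 libraries against a mean of 1.30% in sham and 2.78% at day 7. Krt20 was seen in 3.24% and 24.1% against 0.0293% in sham, and Lcn2 in 1.80% and 7.98% against no cell in sham and 0.0776% at day 7. Other classes held these RNAs too: in day 3 replicate 2 Cdkn1a was seen in 64.1% and Lcn2 in 36.5% of endothelial-like cells, against 53.2% and 7.98% of proximal-tubule-like cells. Cdkn1a was also seen in 4.06% of T/NK-like cells in day 3 replicate 1 and 14.8% in day 3 replicate 2. Spp1, osteopontin, was seen in 56.2% against 40.6% (exact p = 0.3) and Vcam1 in 0.210% against 0.177% (exact p = 0.7), while Cdkn1a, Krt20 and Lcn2 reached the exact p of 0.1.

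The thick ascending limb reabsorbs salt downstream of the proximal tubule, and its cells changed in 205 of 3512 genes at day 3. Lcn2 rose from 58.9 ± 56.8 to 8499.8 ± 14.0 CPM, a log2 fold change of 7.27 ± 0.59. Egf, the growth factor gene made in this segment (ENSMUSG00000028017, chromosome 3, 129677565–129755316), fell from 7689 ± 899.9 to 305 ± 221 CPM (-4.65 ± 0.55). Further ranked rises were Cebpd (4.67), Mt2 (4.66) and Gdf15, with 173 UMIs against 3 (ratio 25.2, counting interval 8.47 to 123). Ranked falls were Sfrp1 (-4.19), Fam107a (-3.62) and Aebp1, with 3 UMIs against 27 (ratio 20.6, counting interval 6.35 to 106). The called genes were 113 higher and 92 lower (626 at an unadjusted p under 0.05), in 26, 23 and 35 sham and 50 and 55 day 3 cells. The edgeR adjusted p-values were 7.33e-07 for Lcn2 and 3.15e-05 for Egf. The count was 123 without sham replicate 3 and 124 without day 3 replicate 2.

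Injured tubule genes rose in 6 of 9 cases in thick-ascending-limb-like cells (8 adjusted over the list alone; median 2.69; S100a11 2.86). NRF2 and glutathione genes rose in 4 of 14 (6 rose and 1 fell adjusted over the list alone; Gclc, which makes glutathione, 4.60; Txn1 1.45). These 2 lists had camera adjusted p-values of 6.44e-21 and 8.01e-06, and adjusted p = 0.0115 and 0.0413 with an estimated correlation. p53 targets rose in 5 of 9 cases (5 adjusted over the list alone; Cdkn1a 3.59; camera adjusted p = 1.74e-08, adjusted p = 0.112 with an estimated correlation). Regulated cell death genes rose in 2 of 9 (Acsl4 1.73, Fth1 1.60; 3 adjusted over the list alone; camera adjusted p = 0.0158, adjusted p = 0.214 with an estimated correlation). Thick ascending limb transport genes fell in 5 of 17 cases (7 fell and 1 rose adjusted over the list alone; Bsnd, a chloride channel subunit, -2.70; camera adjusted p = 2.67e-06, adjusted p = 0.139 with an estimated correlation). Mitochondrially encoded genes fell in 1 of 13 (mt-Co3 -2.94; 4 adjusted over the list alone; camera adjusted p = 6.19e-06, adjusted p = 0.298 with an estimated correlation). The other lists did not pass, among them chemokines (Tnfrsf12a 3.71, Il34 2.89; camera adjusted p = 0.0713), immediate early genes (Socs3 2.93, Klf6 1.42 but 0.88 and not called without day 3 replicate 1, median -0.36, higher by the test, 0.824) and endoplasmic reticulum stress (Calr -1.36 but -0.87 and not called with thinned sums, Hsp90b1 -1.18, 0.0678). Nor did fatty acid oxidation (Eci2 1.90; camera adjusted p = 0.393), respiratory chain (Sdhb -1.12; 0.204), glycolysis (Ldha 1.71; 0.204), cell cycle (0.395), antigen presentation (0.778) and, as free RNA, proximal tubule transporters (0.653).

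At day 7 immediate early genes fell in thick-ascending-limb-like cells, 8 of 21 over all genes and 17 adjusted over the list alone, with a median of -2.45. Atf3, a stress-induced transcription factor (ENSMUSG00000026628, chromosome 1, 191170296–191218039), was at -6.03 ± 0.56 (edgeR adjusted p = 5.51e-06), Junb at -3.03 and Egr1 at -3.41 (-2.26 without day 7 replicate 1), and Pdk4, which restrains pyruvate oxidation, at -3.01. The list's camera adjusted p was 1.70e-39, and the adjusted p was 0.130 with an estimated correlation. Of 3512 genes 12 were called, 1 higher and 11 lower (238 at an unadjusted p under 0.05). Leaving out a library gave 20 (sham replicate 2), 1 (sham replicate 3, Atf3), 41 and 39 (day 3 replicates 1 and 2), 6 (day 7 replicate 2) and 21 (day 7 replicate 3). Antigen presentation (median -1.26, camera adjusted p = 3.16e-04), mitochondrially encoded (-0.43, 0.00233), endoplasmic reticulum stress (-0.13, 0.0133), chemokine (-0.70, 0.0256) and p53 target (-0.41, 0.0394) lists were lower (adjusted p = 0.492 for each with an estimated correlation). The respiratory chain list was higher (median 0.09, camera adjusted p = 0.0394, adjusted p = 0.622 with an estimated correlation). Lcn2 (-3.83, edgeR adjusted p = 0.0789) and Cdkn1a (-2.51, 0.0515) were not called. Injured tubule genes (median -0.45, camera adjusted p = 0.0761) and transport genes (0.04, 0.479) did not pass.

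Endothelial-like cells changed in 232 of 8347 genes at day 3. Mt2 rose by 8.80 ± 0.81 on the log2 scale, Lrg1, a secreted glycoprotein that promotes vessel growth (ENSMUSG00000037095, chromosome 17, 56119678–56122001), by 5.47 ± 0.61. Icam1, which binds leukocytes, rose by 3.33 ± 0.48 (1.35, not called, without day 3 replicate 2), while Npr3 fell by 4.38. The called genes were 159 higher and 73 lower (1221 at an unadjusted p under 0.05), in 326, 286 and 105 sham and 23 and 385 day 3 cells. At Leiden resolution 2 a cluster with Emcn and Rsad2 among its leading genes held 228, 212 and 68 sham and 4 and 8 day 3 cells. That led by Igfbp3 held 10, 4 and 4 against 11 and 271, and that led by Sox17 88, 70 and 33 against 8 and 106. Whether the changes lie within like cells was not tested. Endothelial activation genes rose in 3 of 12 cases (5 rose and 1 fell adjusted over the list alone) and p53 targets in 5 of 20 (14 adjusted over the list alone; Ddit4 2.29, Trp53inp1 1.94, but 0.73 and not called without day 3 replicate 2). Chemokine and NF-kB genes rose in 6 of 17 cases and fell in 1 (12 and 1 adjusted over the list alone, Cxcl2 4.84 with overlapping groups). Interferon genes fell in 2 of 28 cases (8 adjusted over the list alone; Rsad2 -2.43, Ifi27l2a -1.74, but -0.26 and not called with no doublets removed) and antigen presentation genes in 2 of 16 (5 adjusted over the list alone; H2-Aa -3.30, Cd74 -2.55). Immediate early genes rose in 2 of 25 cases with 1 falling (8 and 5 adjusted over the list alone; Socs3 1.86, Hspa1b -2.50).

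Camera adjusted p-values in endothelial-like cells at day 3 were 1.05e-12 for p53 targets, 1.22e-07 for chemokines, 1.22e-07 for interferon, 1.33e-04 for activation, and 0.00196 for antigen presentation and immediate early genes. In the same order these became adjusted p = 0.114, 0.173, 0.367, 0.173, 0.490 and 0.382 with an estimated correlation in camera. Cell cycle (camera adjusted p = 0.783), extracellular matrix (Col4a2 2.08, Col4a1 1.54, 0.302) and, as free RNA, proximal tubule transporters (0.0939, median -0.93 with genes at 0 set to their bound) did not pass. Slc34a1 had 2 UMIs against 107, a ratio of 38.1 (counting interval 10.3 to 319). The count was 66 without sham replicate 2 and 364 and 510.0 without day 7 replicates 1 and 3. It was 4 without day 3 replicate 2, where Lrg1 and Mt2 were still called and Icam1 was not (1.35, edgeR adjusted p = 0.769). H2-Aa and Cd74, genes of antigen-presenting leukocytes, turned to 0.08 and 1.44 with no doublets removed.

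At day 7 endothelial-like cells, 40, 34 and 29 of them, held more proximal tubule RNA. Of 17 transporters, 8 rose (15 adjusted over the list alone), with a median of 3.31 and a camera adjusted p of 3.63e-28 (adjusted p = 0.0470 with an estimated correlation). Slc34a1 went from 30.4 ± 2.62 to 162 ± 58.1 CPM (2.16) and Lrp2, the endocytic receptor megalin, was at 3.31 (2.17, not called, without day 7 replicate 1). Immediate early genes fell in 5 of 25 cases (15 adjusted over the list alone; median -1.18; camera adjusted p = 1.37e-26, adjusted p = 0.0448 with an estimated correlation). The heat shock gene Hspa1a (ENSMUSG00000091971, chromosome 17, 34969190–34972156) was at -3.59 ± 0.39 (edgeR adjusted p = 5.42e-04) and Hspa1b at -3.24. Ranked falls also held Mgp (-3.05) and Notch3, with 1 UMI against 285 (ratio 41.7, counting interval 7.43 to 1654). Of 8347 genes 51 were called, 33 higher and 18 lower (848 at an unadjusted p under 0.05). Leaving out a library gave 5, 27 and 13 (sham replicates 1 to 3) and 2, 3 and 209 (day 7 replicates 1 to 3). Activation (median -0.24 with a gene at 0 set to its bound, camera adjusted p = 0.819), p53 (Cdkn1a -1.89, Gdf15 3.24, 0.909), chemokine (0.648), interferon (0.648), antigen presentation (0.648), extracellular matrix (0.340) and cell cycle lists (0.648) did not pass.

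Mononuclear-phagocyte-like cells, which include resident macrophages and blood-derived monocytes, changed in 1003 of 11675 genes at day 3. Chil3 rose from 20.9 ± 8.12 to 3149 ± 977 CPM (6.97 ± 0.47), fibronectin, Fn1 (ENSMUSG00000026193, chromosome 1, 71585520–71653200), by 7.08 ± 0.79. Arg1, arginase (ENSMUSG00000019987, chromosome 10, 24915221–24927484), went from 2 to 3787 UMIs, a ratio of 1066 (counting interval 295 to 8809). The acute phase gene Saa3 rose by 7.04 (3.26 without day 3 replicate 2), a call lost with sums thinned to the smallest sample. Cxcl9, an interferon-induced chemokine (ENSMUSG00000029417, chromosome 5, 92321347–92328079), went from 119 ± 138 to 0.171 ± 0.0153 CPM (-9.43 ± 1.34). Ciita, the regulator of class II antigen presentation, fell by 4.32, with Mmp13 (-4.05) and Clec4b1 (-3.94). The called genes were 530 higher and 473 lower (2564 at an unadjusted p under 0.05), in 848, 780 and 699 sham and 487 and 1317 day 3 cells. The count was 652 without sham replicate 2. The edgeR adjusted p was 1.16e-06 for Chil3 and 2.85e-06 for Arg1. Cluster 3, led by Ccl4, H2-Eb1, Cd74 and Mmp13, held 87.5% of the class in sham. Clusters 30 and 14, led by Rgs1 and by Fn1, Chil3, Thbs1, Ccl2, Arg1 and Vcan, held 35.3% and 58.3% of the class in day 3 replicate 1 and 72.1% and 22.0% in day 3 replicate 2.

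**Figure D4:**
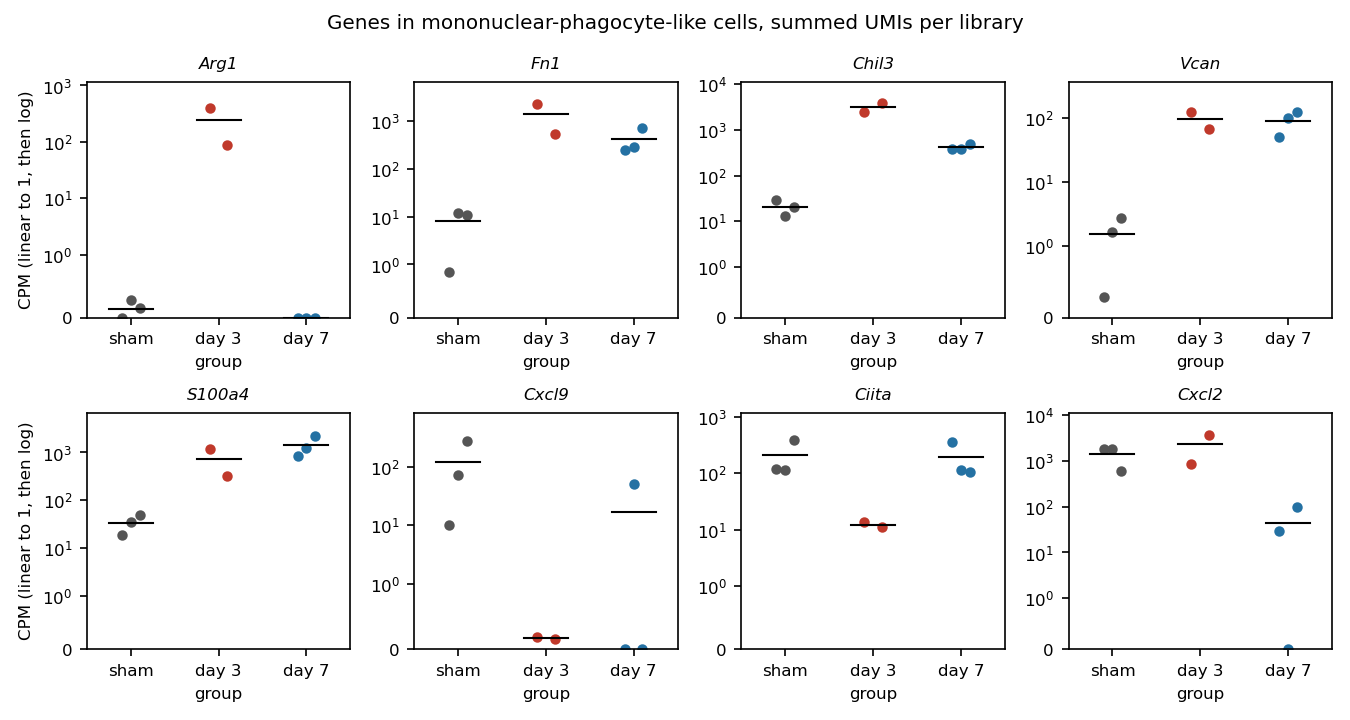
Level of 8 genes in mononuclear-phagocyte-like cells in CPM (vertical axes, linear up to 1 and logarithmic above), 1 dot per library by group (horizontal axes), with bars at group means. Arg1, Fn1 and Chil3 lie higher and Cxcl9 and Ciita lower in both day 3 libraries than in all 3 sham libraries.

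Monocyte-derived genes rose in 10 of 16 cases at day 3 (13 adjusted over the list alone; median 2.71; Thbs1 6.48). p53 targets rose in 10 of 25 cases with 1 falling (14 and 1 adjusted over the list alone; Epha2 5.79, Ddit4 2.14). Glycolysis genes rose in 7 of 15 (9 adjusted over the list alone; the glucose transporter gene Slc2a1 1.95, Slc16a3 2.14) and cell cycle genes in 6 of 30 (14 adjusted over the list alone; Rrm1 1.49, Tyms 1.21, both at 0.80 and not called without day 3 replicate 1). Antigen presentation genes fell in 10 of 19 cases (12 adjusted over the list alone; median -1.28; H2-Eb1 -3.76) and interferon genes in 9 of 28 (15 adjusted over the list alone; Rsad2 -1.91, Gbp3 -1.63). Resident macrophage genes fell in 3 of 14 with 2 rising (6 and 2 adjusted over the list alone; Cd81 -2.20, Cd72 -2.18). Camera adjusted p-values were 1.77e-27, 4.71e-07, 1.03e-06, 1.03e-06, 7.64e-16, 1.47e-08 and 0.00228 in that order. Camera gave adjusted p = 0.0413, 0.0269, 0.136, 0.436, 0.117, 0.238 and 0.238 with an estimated correlation. Immediate early genes were lower as a list (median -0.57, 4 fell and 3 rose, Dnajb1 -2.49, Fosl2 2.33; camera adjusted p = 0.00379, adjusted p = 0.563 with an estimated correlation). Repair-phase genes (5 rose, Spp1 4.95 among them, and 4 fell; camera adjusted p = 0.199), chemokines (2 rose, Ccl2 2.33, and 1 fell; 0.315) and, as free RNA, proximal tubule transporters (0.126) did not pass.

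The few mononuclear-phagocyte-like cells of day 7 (44, 104 and 96) also carried monocyte genes. Of 16, 12 rose against sham (16 adjusted over the list alone) with a median of 3.83. Vcan, versican (ENSMUSG00000021614, chromosome 13, 89655312–89742509), rose by 5.34 ± 0.50, Fn1 by 5.33, S100a4 by 4.98 and Ifitm6 by 3.79. Immediate early genes fell in 18 of 26 cases (23 adjusted over the list alone; Atf3 -3.77, Dnajb1 -2.87). Chemokine and NF-kB genes fell in 10 of 25 with 1 rising (12 and 2 adjusted over the list alone; Cxcl2 -5.12, Nfkbia -2.91). Resident macrophage genes fell in 6 of 14 (9 adjusted over the list alone; Cd81 -2.11, Adgre1 -1.33). The camera adjusted p-values were 6.62e-45, 9.36e-36, 4.26e-10 and 4.26e-10. The 4 lists held in camera at adjusted p = 0.0413, 0.0471, 0.0471 and 0.0421 with an estimated correlation. Among ranked genes Rgs1 (-4.95) and Cd83 (-4.30) fell, Gdf15 had no UMI at day 7 against 613 in sham, at least 11.8-fold lower by the floor over the group. Rn7sk, a small nuclear RNA whose level also set day 7 libraries apart in other classes, rose by 5.02 (2.54 without day 7 replicate 2).

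In those cells proximal tubule transporters, a measure of free RNA, were higher as a list (median 1.42, none called, camera adjusted p = 2.18e-05, adjusted p = 0.365 with an estimated correlation). Antigen presentation genes were lower (median -0.67, camera adjusted p = 1.68e-05, 0.256 with an estimated correlation), 1 of them, H2-DMb1 (-1.40), falling over all genes and 5 adjusted over the list alone. Lower too were cell cycle genes (camera adjusted p = 5.74e-05, 0.456 with an estimated correlation), with Birc5 at 1 UMI against 228 (ratio 13.2, counting interval 2.35 to 523), and p53 targets (0.0200 and 0.163), of which 4 fell, among them Pmaip1 (-2.23). Repair-phase genes were lower (camera adjusted p = 0.0297, 0.233 with an estimated correlation), 2 of them falling, Ctsl (-1.67) and Ccl8, with 3 UMIs against 1500 (ratio 28.9, counting interval 9.88 to 141). The fall of Ccl8 was not called with no doublets removed (-2.77). The medians of these 3 lists, with genes at 0 set to their bound, were -1.37, -0.24 and -0.54. Interferon (camera adjusted p = 0.457) and glycolysis genes (0.579) did not pass. Of 11675 genes 390 were called, 202 higher and 188 lower (2032 at an unadjusted p under 0.05). Leaving out a library gave 257 and 233 (sham replicates 1 and 2), 683 and 657 (day 3 replicates 1 and 2), and 151 and 116 (day 7 replicates 2 and 3). Clusters 14, 3 and 10 held 20.5%, 61.4% and 18.2% of the class in day 7 replicate 1, 40.4%, 8.7% and 51.0% in replicate 2 and 46.9%, 49.0% and 4.2% in replicate 3.

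T/NK-like cells changed in few genes at day 3. Bbc3, a pro-apoptotic p53 target, rose by 2.21 ± 0.40 on the log2 scale, Pik3ip1 by 2.11, Txnip by 2.05 (1.24, not called, without day 3 replicate 2) and the cytokine receptor gene Il7r by 1.92, and Pclaf, a gene of dividing cells, fell by 5.53, each with an edgeR adjusted p of 0.0478. These 5 were all that was called of 6776 (671 at an unadjusted p under 0.05), in 155, 125 and 299 sham and 513 and 30 day 3 cells. Leaving out a library gave 3, 0 and 27 (sham replicates 1 to 3) and 8, 0 and 18 (day 7 replicates 1 to 3). None was called at Leiden resolution 2, with the automatic Scrublet threshold or with 200 UMIs per cell. p53 targets were higher as a list of 17 (1 rose, 2 adjusted over the list alone, median 0.56, camera adjusted p = 1.06e-05, adjusted p = 0.0280 with an estimated correlation). Cell cycle (median -1.35, none called, 12 fell adjusted over the list alone; camera adjusted p = 1.91e-08), interferon (-0.51; 0.0209) and cytotoxic genes (-0.14; 0.0292) were lower, with adjusted p = 0.622, 0.676 and 0.676 with an estimated correlation. Immediate early genes (camera adjusted p = 0.664), activation genes (median -0.08, mean 0.21; 0.656) and, as free RNA, transporters (median 0.19, lower by the test, 0.981) did not pass.

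At day 7 T/NK-like cells had lower levels of activation genes. Of 10 activation and exhaustion genes 3 fell (5 adjusted over the list alone; median -1.11), with the inhibitory receptor gene Ctla4 at -2.48 ± 0.49 and Tnfrsf4 at -2.27. Of 25 immediate early genes 7 fell (17 adjusted over the list alone; median -1.61; Junb -2.56, Ier2 -2.20, Hspa1b -2.96). Gadd45b, a stress-induced gene (ENSMUSG00000015312, chromosome 10, 80930073–80932204), was at -3.08 (edgeR adjusted p = 5.18e-04), Pmaip1 at -3.53 and Hilpda at -3.34. Cytotoxic genes fell in 1 of 15 cases, Ifng, interferon gamma, at -2.16. Camera adjusted p-values were 1.59e-07, 2.05e-22 and 1.69e-04, and adjusted p = 0.0160, 0.131 and 0.256 with an estimated correlation. Cell cycle genes (median 0.35, none called, camera adjusted p = 5.20e-07) and, as free RNA, proximal tubule transporters (1.44, 5 rose and 1 fell adjusted over the list alone, Slc34a1 1.64, not called, 1.69e-04) were higher, with adjusted p = 0.256 and 0.190 with an estimated correlation. p53 targets and interferon genes did not pass (both camera adjusted p = 0.0568). The ranked rises were Rn7sk (7.27), Lars2 (3.62), Mir6236 (3.48) and Hist1h2ae (3.21). Of these Lars2 and Mir6236 also led proximal-tubule-like cluster 17 and Rn7sk cluster 20, where most cells came from day 7 replicates 3 and 2. Of 6776 genes 81 were called, 18 higher and 63 lower (811 at an unadjusted p under 0.05). Leaving out a library gave 30 and 46 (sham replicates 1 and 2), 141 (day 3 replicate 2), and 32, 32 and 126 (day 7 replicates 1 to 3). Clusters 1 and 15 held the class in every group, cluster 1 with 85.1%, 76.2% and 89.9% in sham, day 3 and day 7. At Leiden resolution 2 the class split further. The cluster led by Cd28, Trbc2 and Il7r held 132, 102 and 223 sham and 13, 0 and 50 day 7 cells. That led by Cd3d and Cxcr6 held 1, 3 and 26 against 455, 4 and 53. The cluster led by Gzma held 18, 20 and 48 against 68, 0 and 26. Another, with a median of 795 UMIs, held 4, 0 and 2 against 130, 167 and 4. Whether the day 7 changes lie within like cells was not tested.

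In the other classes with enough cells edgeR called 443 of 9206 genes in dendritic-like cells at day 3 (244 higher, 199 lower) and 14 at day 7, 581 of 8527 in stromal-like cells (242 higher, 339 lower) and 57 of 4031 in neutrophil-like cells (47 higher, 10 lower) at day 3. It called 0 of 8633 at day 3 (1192 at an unadjusted p under 0.05) and 46 at day 7 (9 higher, 37 lower) in cells resembling intercalated or collecting duct principal cells, and 0 of 5989 at day 7 (662 at an unadjusted p under 0.05) in those resembling distal convoluted or connecting tubule. DESeq2 was not run in these classes.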

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

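Of the tests in this part, that of RNA from other cell types was chosen before its result was seen, and those of single libraries, depth, handling, the UMI minimum, tubule recovery and other splits only after. The results listed first were picked out by one rule, that the effects of cisplatin at day 7 and at day 3, both against sham, differed in the contrast of day 7 with day 3 at an edgeR adjusted p under 0.05. Effects differed for 1095 genes in proximal-tubule-like, 423 in thick-ascending-limb-like, 312 in endothelial-like, 382 in mononuclear-phagocyte-like and 153 in T/NK-like cells. Among class shares the rule picked distal convoluted or connecting tubule (6.34), mononuclear-phagocyte-like (-3.59), neutrophil-like (-5.12) and stromal-like cells (-3.08), as log2 changes from day 3 to day 7.

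Of the genes named for proximal-tubule-like cells, those with lower values at day 7 than at day 3 were, in log2 fold changes, the injury genes Krt20 (-11.07), Lcn2 (-8.87), Krt18 (-5.99) and Havcr1 (-5.47), the p53 targets Btg2 (-7.35), Psrc1 (-5.30), Cdkn1a (-4.95) and Trp53inp1 (-3.04), and the ranked genes Sprr1a (-9.02), Gsta1 (-7.89) and Ces2e (-5.02). Chemokine and receptor genes were Cxcl2 (-9.35), Cxcl1 (-6.79) and Tnfrsf12a (-4.90), interferon genes Rsad2 (-5.76), Isg15 (-3.94) and Bst2 (-2.48), with B2m at -1.78, stress genes Atf3 (-6.62), Trib3 (-4.97) and Ppp1r15a (-4.63), immediate early genes Ier5 (-3.87) and Zfp36 (-2.85), and detoxification genes Mt2 (-7.08), Mt1 (-4.91), Ephx1 (-4.88) and Srxn1 (-3.22). Timp1 was at -8.34, Mlkl at -4.94 and Cd24a at -4.71. Without the cluster led by Krt20, an alternative added after seeing the data, calls between the days were lost for Rsad2 (-0.17), Isg15 (-1.11), Cd24a (-0.99), B2m (-1.58) and Sprr1a (-3.20). Trib3 and Mlkl did not pass filterByExpr there and were not tested. Low counts stand behind Cxcl2, with 3 UMIs against 893 (ratio 500.6, counting interval 171 to 2432), and Timp1, with 1 UMI against 180.0 (ratio 303, counting interval 53.6 to 12020). Higher at day 7 than at day 3 were Gatm (5.46), Slc22a28 (5.46), Clec2h (5.39), Inmt (4.82), Dpep1 (3.64), Acsm2 (2.83), Acsm1 (1.60) and Slc26a1 (2.23). Of these Gatm (5.01), Clec2h (4.83), Dpep1 (3.17), Acsm1 (1.32) and Slc26a1 (1.90) lost their call without that cluster.

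The rise of p53 targets in proximal-tubule-like cells at day 3 was set against 3 technical explanations. The list's median log2 ratio to the sham mean was 2.54 in the lower and 2.92 in the higher of the 2 day 3 libraries, which argues against a single library carrying it. RNA of 5 other classes gave 0.321% of the called targets' level in the library where it gave most, which argues against RNA from other cells. After thinning of the sums the median was 2.74. Thinning keeps the expected proportions of genes within a sum, so it cannot decide whether depth per cell played a part. The data are consistent with a p53 response of tubule cells to cisplatin, a hypothesis found and tested on the same data. Whether the change lies within cells or in which tubule cells survive and are captured was not tested, and the clusters that hold the class differ between sham and day 3.

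The fall of immediate early and dissociation genes at day 7 was seen in 5 of 5 classes with a list median under -1, and handling or dissociation that differed between libraries cannot be told apart from the stage, since each library has 1 group and no handling times are given. Per library the day 7 medians against the sham mean were -2.83, -1.62 and -1.38 in proximal-tubule-like cells, where sham libraries had -0.52, 0.23 and -0.16, and -1.96, -2.37 and -0.65 in T/NK-like cells, while the summed level in proximal-tubule-like cells overlapped, at 3375 CPM in day 7 replicate 3 and 3290.0 CPM in sham replicate 1. The way this test is read was changed from the summed level to the medians after both were seen, and the question stays open either way. After thinning of the sums the median in proximal-tubule-like cells was -2.04. Since thinning keeps the expected proportions within a sum, this cannot decide on depth per cell. A lower stress response at day 7 stays untested beside handling and depth.

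The smaller mononuclear-phagocyte-like share at day 7 was set against 2 technical explanations. With cells from 200 UMIs on, the log2 change was -3.49, which argues against the UMI minimum. If more proximal tubule cells had been recovered and all other classes alike, the ratio of mononuclear-phagocyte-like to lymphocyte-like cells would have stayed. Its mean log2 value changed by -3.73, from 2.45, 2.64 and 1.23 in sham to -3.92, -0.48 and -0.47 at day 7. The 2 day 3 libraries stood at -0.08 and 5.46, a spread within 1 group that limits what this shift can show. Dissociation that releases or keeps macrophages less well at day 7 was not tested, and neither was a loss of these cells in the tissue. The limit of 50% mitochondrial UMIs removed 45.2%, 47.6% and 39.8% of sham but 20.4%, 2.37% and 17.7% of day 7 barcodes. A wider limit was not tested either.

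In the comparison of day 7 with sham, 3 against 3 libraries make 10 splits, too few for a share under 0.05. The count of called genes was as large in 10 splits for proximal-tubule-like cells (real 0, highest other 0) and in 1 split each, the real one, for thick-ascending-limb-like (real 12, highest other 1), endothelial-like (51 and 3), mononuclear-phagocyte-like (390 and 0) and T/NK-like cells (81 and 0), and for changed class shares (4 and 0). For gene lists in proximal-tubule-like cells 7 of the 10 splits passed as many as the real 7, and the split of sham replicate 1 with day 7 replicates 1 and 3 against the rest passed 11, more than the real one.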

How the results depend on the processing

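Of the tests in this part, those with 200 UMIs per cell and without the cluster led by Krt20 were chosen only after the data were seen. Counts of called genes moved in both directions, in data with 2 or 3 libraries per group and class sums between 31808 and 40571962 UMIs. Where a count below moved and no reason is given, the cause was not tested. Where leaving out a library leaves 1 at day 3, that lone sample is assumed to vary like the other groups. Among single named genes over all settings 4249 values kept direction and side of the threshold, 195 kept direction and passed it newly, 527 kept direction and no longer passed, and 7 reversed. Those 7 were Lcn2 in proximal-tubule-like cells at day 7 (-0.74 at Leiden resolution 2 and -0.82 without day 7 replicate 2, with a range of -0.82 to 1.35 over the libraries left out), Mt2 there (0.29 without sham replicate 1, range -2.97 to 0.29), and H2-Aa and Cd74 in endothelial-like cells at day 3 (0.08 and 1.44 with no doublets removed, 0.22 and 1.63 with the automatic Scrublet threshold). RLE size factors and TMM over the classes kept every count within 1.5 times. The difference in the share of proximal-tubule-like cells with a Havcr1 UMI, day 3 minus sham, was 2.59 percentage points with cells thinned to 500 UMIs and 16.8 with none thinned, against 5.36, at the same exact p of 0.1. Under 25% mitochondrial UMIs thick-ascending-limb-like cells could not be fitted.

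With DESeq2 the counts for proximal-tubule-like cells were 1773 at day 3 (1013 higher, 760.0 lower), 156 at day 7 (60 higher, 96 lower) and 2144 between the days (867 higher, 1277 lower), against 620, 0 and 1095 with edgeR. For other classes they were 130 thick-ascending-limb-like at day 3, 68 and 22 endothelial-like at day 3 and 7 (10 higher, 12 lower at day 7), 639 mononuclear-phagocyte-like at day 7, and 28 T/NK-like at day 3 (7 higher, 21 lower), with 29 genes called the same way at both days in proximal-tubule-like cells. Without filterByExpr more genes were tested and the counts were 2625, 619 and 3081 for proximal-tubule-like cells at day 3, at day 7 and between the days, 56 for thick-ascending-limb-like at day 7, 677 and 318 for endothelial-like, 1571 and 852 for mononuclear-phagocyte-like and 133 and 243 for T/NK-like cells at day 3 and 7, with 201 genes called the same way at both days. With thinned sums, which discard counts, they were 367 at day 3 and 691 between the days for proximal-tubule-like cells, 49 for thick-ascending-limb-like at day 3, 9 and 3 for endothelial-like, 95 and 146 for mononuclear-phagocyte-like, and 2 and 42 for T/NK-like cells. With only the 2 groups compared they were 987 at day 3 and 395 between the days for proximal-tubule-like cells, 6 for thick-ascending-limb-like at day 7, and 542 and 10 for endothelial-like cells.

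With no doublets removed the counts were 19 for endothelial-like cells at day 7 and 18 and 147 for T/NK-like cells at day 3 and 7. T/NK-like cells at day 3 had 0 called at Leiden resolution 2, with the automatic Scrublet threshold and with 200 UMIs per cell. Under 25% mitochondrial UMIs 413 genes were called in proximal-tubule-like cells at day 3, and without the cluster led by Krt20 127 at day 3 and 504 between the days. With an estimated correlation no gene list passed in proximal-tubule-like cells, 0 at day 3, 0 at day 7 and 0 between the days against 10, 7 and 13 at the preset one. With the exact permutation test no class share passed, 0, 0 and 0 against 1, 4 and 4, a test that cannot go below p = 0.1 here.

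The replicate number as a block gave 299 called genes at day 3 and 457 between the days in proximal-tubule-like cells, 27 in thick-ascending-limb-like cells at day 7, 106 and 23 in endothelial-like cells at day 3 and 7, 2 in T/NK-like cells at day 3, and 2 changed class shares at day 3. Deviations of same-numbered proximal-tubule-like sums from their group means correlated by -0.104 to 0.240, 3 of 7 over 0.1, and those of differently numbered ones by -0.240 to 0.198, so not every library correlated best with its own number, and the libraries share only a number.

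Leaving out each library in turn gave ranges of 0 to 2157 called genes at day 3, 0 to 7 at day 7 and 72 to 2939 between the days in proximal-tubule-like cells, 123 to 208 and 1 to 41 in thick-ascending-limb-like, 4 to 510.0 and 2 to 209 in endothelial-like, 652 to 1068 and 116 to 683 in mononuclear-phagocyte-like, and 0 to 27 and 30 to 141 in T/NK-like cells at day 3 and day 7. Gene lists passed in 8 to 12 cases at day 3, 6 to 12 at day 7 and 12 to 14 between the days in proximal-tubule-like cells, and class shares in 1 to 2, 3 to 6 and 2 to 8. Genes called the same way at both days numbered 0 to 3, and the difference in the share of proximal-tubule-like cells with a Havcr1 UMI, day 3 minus sham, was 3.33 to 7.39 percentage points against 5.36 with all libraries.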

Other observations

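The tests in this part were planned, while the lists described and the 5 genes named last were chosen only after their values were seen. From day 3 to day 7 the list of cell division genes was higher in T/NK-like cells and lower in mononuclear-phagocyte-like cells. Cell cycle genes rose in 7 of 25 cases in T/NK-like cells (median 1.85; camera adjusted p = 2.16e-17, adjusted p = 0.154 with an estimated correlation) and fell in 8 of 30 in mononuclear-phagocyte-like cells (median -2.51 with genes at 0 set to their bound; camera adjusted p = 3.58e-15, adjusted p = 0.184 with an estimated correlation). p53 targets fell in 3 of 17 and 8 of 25 cases, with camera adjusted p-values of 1.40e-07 and 1.97e-10, and adjusted p = 0.0102 and 0.0393 with an estimated correlation. In mononuclear-phagocyte-like cells antigen presentation genes were higher again at day 7, 4 of 19 rising (median 0.70; camera adjusted p = 1.97e-10, adjusted p = 0.134 with an estimated correlation).

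In thick-ascending-limb-like cells injured tubule genes were lower at day 7 than at day 3 in 8 of 9 cases (median -2.27) and transport genes rose in 4 of 17 (median 0.84), with camera adjusted p-values of 1.31e-17 and 5.54e-04, and adjusted p = 0.0428 and 0.243 with an estimated correlation. In endothelial-like cells proximal tubule transporters, a measure of free RNA there, were higher at day 7 than at day 3 in 10 of 17 cases (median 4.74 with genes at 0 set to their bound). Among p53 targets of proximal-tubule-like cells chosen after their values were seen, Phlda3 (5.68), Eda2r (4.79), Ccng1 (2.98) and Mdm2 (1.99), the feedback inhibitor of p53, rose at day 3, with edgeR adjusted p-values of 0.0170 for Phlda3 and 0.0103 for the other 3, while Bax was at 0.99 (edgeR adjusted p = 0.0742).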
